A study of Homo sapiens with 6 samples.

How the data were processed

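RNA was sequenced from 6 cultures of the myeloma line ARP-1, with 3 libraries in the TRIP13-OE group and 3 in the EV group. Groups and replicate numbers were taken from the sample titles. The deposited table of raw counts holds whole-number counts per gene symbol, and the submitters' processing notes name the genome build hg19 and the tool Cufflinks, with no version. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart, and genes with close copies, such as HLA genes, are uncertain. The deposited FPKM table holds, for 100% of the 15366 genes checked (relative tolerance 1e-06), the deposited count divided by the library's total and by 1 length per gene, so it is not independent of the counts and carries no scaling for composition.

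Totals were 17520739, 17380257 and 19115803 counts in TRIP13-OE replicates 1 to 3 and 18642838, 19102607 and 17557006 in EV replicates 1 to 3. The 10 most abundant genes took 4.10% to 4.63% of the counts. Both tables hold 16271 genes, and each has at least 1 count. The gene symbols were looked up in the RefSeq gene table of the GRCh38 assembly, and 16080 genes (98.8%) received a chromosome. Because the table's assembly differs from the submitters' build, it was used only for symbols, chromosome membership and gene order, and no coordinates are given.

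Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM factors (0.945 to 1.042) and the default expression filter, which kept 12482 genes. The model had the group as its only term, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 0.294. SEs were derived from the log2 fold change and its F statistic. For the gene lists, limma 3.58.1's camera was run on log2 CPM, with a preset correlation of 0.01 and two-sided p-values adjusted over the 25 lists with at least 5 tested members. The number of members past the test was counted both over all genes and adjusted over the list alone. The 28 lists held 725 entries, of which 679 were in the tables. They covered ribosomal proteins, proteasome subunits, the spindle checkpoint, mitosis, replication, double-strand break repair, NF-kB targets, the unfolded protein response, the ATF4 response, heat shock proteins, p53 targets, the BCL2 family, drug efflux, plasma cell, B cell, immunoglobulin, T and NK, myeloid and stromal markers, interferon-stimulated genes, MHC class I, ribosome biogenesis, the respiratory chain, mitochondrial genes, glycolysis, cholesterol synthesis, immediate early genes and histones. Calls per chromosome were compared by Fisher's exact test.

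The groups, tests, gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. Named are TRIP13 and RPS3. Of the genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, the rule takes the 10 with the largest log2 fold change in each direction and the 5 others with the smallest p in each. It also takes up to 4 members of each list by p. Some genes that the rule takes are not reported here. Single intervals for few counts cover counting error only, at a level of 95%.

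The tests were run on simulated counts drawn from the means and library sizes of the comparison of TRIP13-OE with EV, with known log2 changes of 1, 2 or 4. These changes were put only in genes with a mean log2 CPM of at least 2. The members of the unfolded protein response list were also lowered, whatever their level, and were not counted as false calls. The dispersion of each gene was that of these libraries, but genes varied independently, so the difference of EV replicate 1 was not simulated. Over 12341 genes, edgeR recovered 26.9% of 67 genes with a log2 change of 1, 89.6% of 67 with 2 and 100% of 66 with 4, and made 11 false calls. DESeq2 recovered 50.7%, 95.5% and 100% of the same genes and made 58 false calls over 12480 genes. With no simulated change edgeR made 0 calls.

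Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other expression filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, a stricter threshold, the replicate number as a block, an estimated correlation or fry for the lists, and leaving out each library. Limma-voom with sample weights, the gene lists with upper-quartile factors and with library totals only, and an estimated correlation with each library left out, were added after the data were seen. Of the libraries and sample columns, none was left out. Figures were drawn with matplotlib 3.10.9.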

Results

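Transcript levels were measured by RNA sequencing in ARP-1 cells, a line established from multiple myeloma, a cancer of plasma cells. The series compared 3 libraries of cells stably transfected to overexpress TRIP13 (TRIP13-OE) with 3 libraries of cells carrying the empty vector (EV). TRIP13 is an ATPase that remodels MAD2 and related proteins and takes part in the spindle checkpoint. The submitters describe the cultures of each arm as independent, but whether each came from its own transfection is not given in the sources used here, so the p-values measure the spread between these libraries. The total count per library ranged from 17380257 in TRIP13-OE replicate 2 to 19115803 in TRIP13-OE replicate 3, and 12482 of 16271 genes had enough counts to be tested. Levels are CPM, counts divided by the scaled library size, given as mean ± SD over n = 3 libraries, and changes are log2 fold changes of TRIP13-OE over EV with their standard error (SE).

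TRIP13 itself was measured first, as a check of the labels. It stood at 1332, 1249 and 1315 CPM in TRIP13-OE replicates 1, 2 and 3, and at 145, 108 and 56.2 CPM in EV replicates 1, 2 and 3. The means were 1299 ± 43.8 and 103 ± 44.8 CPM (SD, n = 3), a log2 fold change of 3.65 (SE 0.34), or 12.6-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0133). The adjusted p rose to between 0.0758 and 0.0971 when TRIP13-OE replicate 1, 2 or 3 or EV replicate 2 was left out, with log2 fold changes of 3.63 to 3.69. Over all alternatives the adjusted p ranged from 9.34e-24 to 0.110.

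RPS3, the small-subunit ribosomal protein named in the title of the series, ranked 40 of the 12482 tested genes by mean level. Its level was 1339 ± 56.8 CPM in TRIP13-OE and 1377 ± 62.1 CPM in EV (SD, n = 3). The log2 fold change of −0.04 (SE 0.12) was smaller than the spread between libraries (edgeR, adjusted p = 0.881), with a 95% interval of −0.32 to 0.24. The sign turned with the scaling, to 0.05 with upper-quartile factors and 0.03 with library totals only or on FPKM values. Of the 78 cytosolic ribosomal protein genes tested, 0 passed the test over all genes and 0 passed when adjusted over the list alone, 6 had an unadjusted p under 0.05, and DESeq2 called 0 higher and 2 lower (camera adjusted p = 0.717). The members with the smallest p were RPSA at −0.45 (SE 0.14, adjusted p = 0.136) and RPLP0 at −0.42 (SE 0.13, adjusted p = 0.136). Many of these genes have processed pseudogenes, so their counts may include reads from copies.

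**Figure D1:**
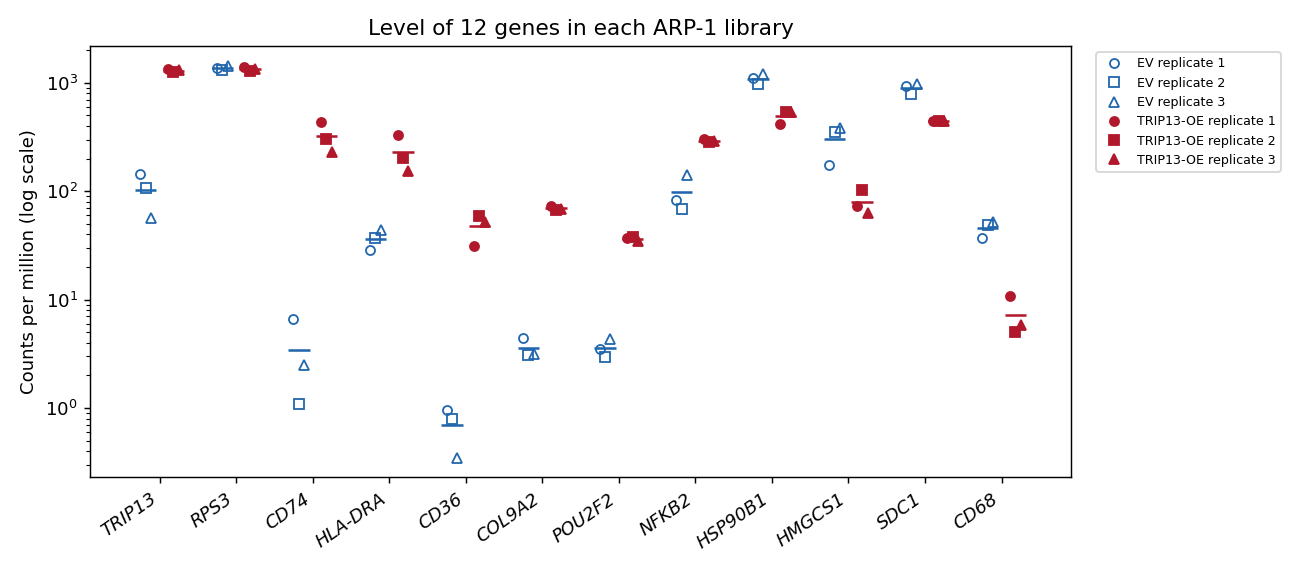
Level of 12 genes in CPM on a log scale in each of the 6 libraries, with open blue symbols for EV, filled red symbols for TRIP13-OE, and a line at each group mean. TRIP13 lay between 1249 and 1332 CPM in TRIP13-OE and between 56.2 and 145 CPM in EV, and RPS3 overlapped between the groups.

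Among the genes past the edgeR test, more were higher than lower in TRIP13-OE, while the median log2 fold change of all tested genes was −0.02. The test called 147 genes higher and 33 lower at an adjusted p under 0.05 (81.7% higher; 54.4% of the calls by DESeq2 and 52.0% of those without EV replicate 1), and 138 of the former and 24 of the latter changed at least 2-fold. The 10 genes with the largest increases under the naming rule had EV means of 0.0387 to 6.52 CPM. CD74, the invariant chain that chaperones MHC class II molecules, rose from 3.41 ± 2.88 to 324 ± 106 CPM (log2 fold change 6.57, SE 0.67, adjusted p = 0.0174; 7.50 without EV replicate 1, which held 6.64 CPM). CD36, a fatty acid and lipoprotein receptor, rose from 0.70 ± 0.32 to 47.7 ± 14.5 CPM (6.07, SE 0.43, adjusted p = 0.00708). SERPINA1, which encodes alpha-1 antitrypsin, had 2 counts over the EV libraries, both in EV replicate 3, and 667 over the TRIP13-OE libraries, a ratio of 325 with a 95% counting interval of 89.6 to 2689. The collagen genes COL6A3 and COL9A2 rose by 4.97 (SE 0.63) and 4.29 (SE 0.21) on the log2 scale, and COL9A2 had the smallest p of all genes (adjusted p = 0.00147). The junction protein gene JAM2, the tyrosine catabolism gene HPD, the germ cell gene TEX19, the transcription factor gene TP63 and FILIP1L rose by 4.94, 4.74, 4.53, 4.39 and 4.22, with JAM2 at 5.63 and FILIP1L at 5.25 without EV replicate 3 and TEX19 at 5.42 without EV replicate 1. Among the genes with the smallest p were POU2F2, a B lineage transcription factor, at 3.34 (SE 0.21), GCSAM, a germinal centre signalling gene, at 3.87 (SE 0.30), and IGFBP4 at 3.45 (SE 0.31). SMAP2 and FSD1 rose by 1.95 (SE 0.15) and 2.07 (SE 0.19).

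On the lower side, KIF26B, a kinesin family gene, fell from 8.86 ± 6.39 to 0.194 ± 0.193 CPM (log2 fold change −5.45, SE 0.91, adjusted p = 0.0441; −6.61 without TRIP13-OE replicate 3 and −4.79 without EV replicate 3). CD68, a lysosomal glycoprotein used as a macrophage marker, fell from 45.8 ± 7.69 to 7.27 ± 3.17 CPM (−2.65, SE 0.33, adjusted p = 0.0281). ARFGEF3, DCC and TFEC fell by 3.31, 2.33 and 2.16 on the log2 scale. SDC1, which encodes the plasma cell surface proteoglycan CD138, fell from 899 ± 101 to 445 ± 3.77 CPM (−1.01, SE 0.13, adjusted p = 0.0288). BHLHA15, a transcription factor gene of secretory cells, fell from 134 ± 26.5 to 44.3 ± 4.73 CPM (−1.59, SE 0.19, adjusted p = 0.0247). FICD, FKBP11, TXNDC11 and SSR3 stood at −1.66 (SE 0.26), −1.65 (SE 0.26), −1.08 (SE 0.14) and −0.90 (SE 0.13). ALDH5A1, ECM1 and PLPP5 fell by 1.59, 1.58 and 1.24.

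The EV libraries were not alike. EV replicate 1 differed over 4-fold from EV replicate 2 at 625 genes and from EV replicate 3 at 918 genes, while EV replicates 2 and 3 differed at 98 genes and pairs of TRIP13-OE libraries at 8 to 65 genes. On the first principal component, with 52.9% of the variance, EV replicate 1 stood at −18.9, near the TRIP13-OE libraries at −29.1, −37.7 and −39.1, and EV replicates 2 and 3 stood at 56.1 and 68.7. Without EV replicate 1, edgeR called 1519 genes higher and 1400 lower, which included all 180 of the genes called with it. Leaving out TRIP13-OE replicate 1, 2 or 3, EV replicate 2 or EV replicate 3 gave 4, 1, 1, 1 and 74 higher genes and 0, 0, 0, 0 and 9 lower genes.

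**Figure D2:**
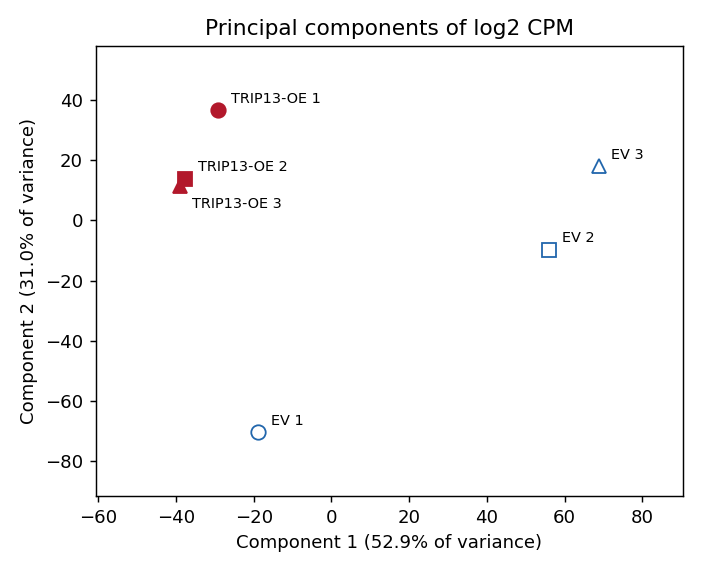
The first and second principal components of log2 CPM over the tested genes, with 52.9% and 31.0% of the variance, for the 3 TRIP13-OE libraries (filled red) and the 3 EV libraries (open blue). EV replicate 1 lies at −70.4 on the second component, apart from both the TRIP13-OE libraries and EV replicates 2 and 3.

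To see which cell functions the changed genes belonged to, 28 gene lists fixed before the data were examined were compared, and 25 had at least 5 tested members. The camera test, which sets a list's log2 fold changes against those of the other genes, called 7 of the 25 lists with its preset inter-gene correlation of 0.01. With a correlation estimated for each list it called 0 (1 list at an unadjusted p under 0.05), so each called list is given with both p-values.

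Of the 12 tested B cell markers, 4 rose over all genes and 7 when adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.578 with an estimated correlation). The members that rose over all genes belong to the MHC class II pathway, which presents antigen to helper T cells. They were CD74, HLA-DRA at 229 ± 91.4 against 36.6 ± 7.57 CPM (log2 fold change 2.64, SE 0.32), HLA-DRB1 at 4.65 (SE 0.72; 5.54 without EV replicate 1) and CIITA, the transactivator of class II genes, at 123 ± 23.4 against 30.9 ± 12.6 CPM (3.99-fold). The surface B cell genes CD22 and CD79B had means of 0 and 0.0375 CPM in TRIP13-OE. EV replicate 1 was below all 3 TRIP13-OE libraries at 7 of the 12 members. Of the 15 genes of antigen presentation by MHC class I, 3 rose over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.0212; adjusted p = 0.930 with an estimated correlation). HLA-B and HLA-F rose by 1.64 (SE 0.22) and 2.20 (SE 0.39), and EV replicate 1 was below all 3 TRIP13-OE libraries at 8 members. The HLA genes are close copies of each other, so the division of reads among them is uncertain. Without EV replicate 2 the class I list no longer passed (adjusted p = 0.105).

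Of the 26 tested NF-kB target genes, 5 rose over all genes and 13 when adjusted over the list alone (camera adjusted p = 1.21e-08; adjusted p = 0.578 with an estimated correlation). NFKB2, which encodes the p100 subunit, rose from 97.7 ± 38.8 to 293 ± 9.16 CPM (1.58, SE 0.27, adjusted p = 0.0454). The co-regulator BCL3, the inhibitor NFKBIE and the activation marker CD83 rose by 1.97 (SE 0.23), 1.09 (SE 0.16) and 1.82 (SE 0.30). The 5th gene, NFKBIZ, at 3.13 (SE 0.53; 3.72 without EV replicate 3), was named after its value was seen. EV replicate 1 was below all 3 TRIP13-OE libraries at 25 of the 26 members. EV replicate 3 was the EV library nearest to TRIP13-OE, with a median deviation of the list from the mean of the 6 libraries of 0.04, against −1.08 and −0.81 in EV replicates 1 and 2 and 0.58 to 0.61 in TRIP13-OE, and 16 members were higher and 1 was lower in all TRIP13-OE libraries than in all EV libraries (the groups did not overlap at 28.0% of all tested genes, against 10% by chance, in either direction). Of the 27 tested genes of glycolysis and hypoxia, 0 passed over all genes (10 at an unadjusted p under 0.05, 5 higher by DESeq2) and 3 rose when adjusted over the list alone, namely ENO2 at 1.99 (SE 0.46), ADM at 0.90 (SE 0.21) and CA9 at 3.97 (SE 1.01). CA9 stood at 14.7, 2.87 and 2.38 CPM in TRIP13-OE replicates 1, 2 and 3 against 0.415 ± 0.339 CPM in EV, and at 2.63 on the log2 scale without TRIP13-OE replicate 1 and 4.66 without EV replicate 2. The camera adjusted p was 0.000433, and the adjusted p = 0.671 with an estimated correlation. EV replicate 1 was below all 3 TRIP13-OE libraries at 18 of these members.

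Of the 25 genes of the unfolded protein response, which folds and quality-checks secreted proteins, 3 fell over all genes and 16 when adjusted over the list alone (camera adjusted p = 7.16e-11; adjusted p = 0.578 with an estimated correlation). With TMM, RLE and upper-quartile factors and with library totals only, 0 of the 25 had a log2 fold change above 0, and the median was −0.61 with TMM. The chaperone HSP90B1 fell from 1096 ± 123 to 500 ± 71.9 CPM (−1.13, SE 0.16, adjusted p = 0.0309), and PDIA4 and HYOU1 fell by 0.84 (SE 0.14) and 0.89 (SE 0.15). PDIA6, at 931 ± 55.4 against 2160 ± 674 CPM, did not pass over all genes (adjusted p = 0.0559). Of the 23 tested cholesterol synthesis genes, 3 fell over all genes and 19 when adjusted over the list alone (camera adjusted p = 1.17e-11; adjusted p = 0.578 with an estimated correlation). HMGCS1 fell from 303 ± 111 to 79.8 ± 20.3 CPM (−1.92, SE 0.33), and IDI1 fell by 1.42 (SE 0.20). EV replicate 1 was above all 3 TRIP13-OE libraries at 22 members of the unfolded protein response list and 19 of the cholesterol list. The list of ribosome biogenesis and MYC targets was lower by camera (adjusted p = 0.0309; adjusted p = 0.930 with an estimated correlation), with 0 of 26 members past the test over all genes or when adjusted over the list alone, 3 at an unadjusted p under 0.05 and 1 lower by DESeq2. EV replicate 1 was above all 3 TRIP13-OE libraries at 25 of these 26 members, and the list no longer passed without it (adjusted p = 0.901) or without TRIP13-OE replicate 1 (adjusted p = 0.379).

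**Figure D3:**
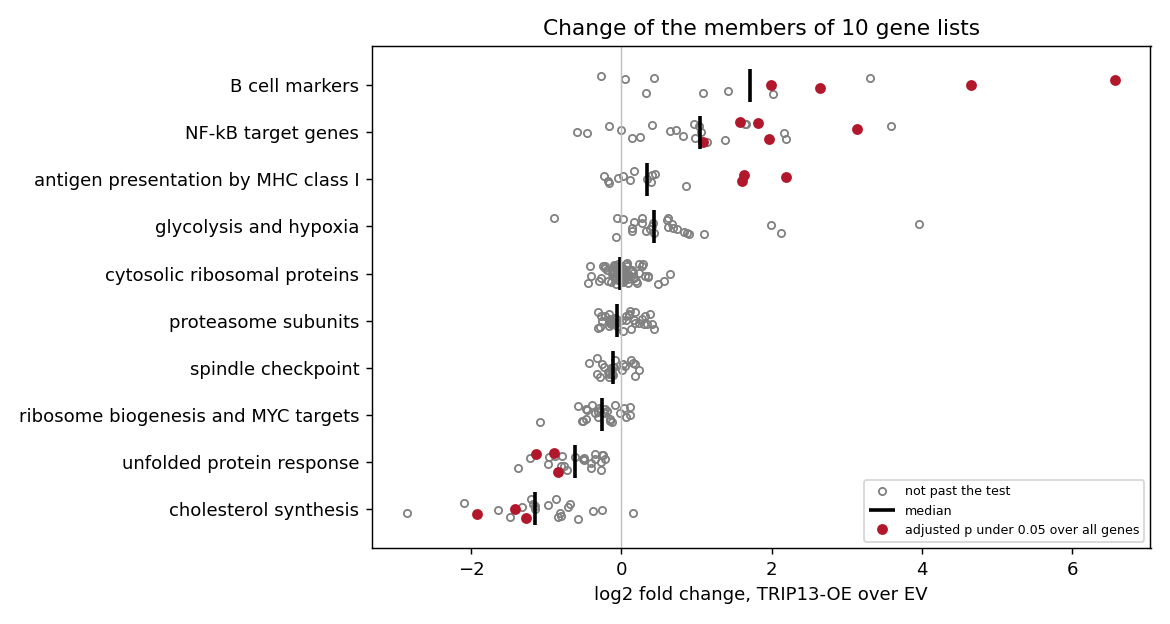
Log2 fold change of TRIP13-OE over EV for each tested member of 10 gene lists, with a black line at the list's median and filled red points for members past the test over all genes. The medians ran from −1.15 for cholesterol synthesis to 1.71 for B cell markers, and that of the cytosolic ribosomal proteins was −0.02.

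With all 6 libraries, the lists that camera did not call included those closest to the known roles of TRIP13. In the spindle checkpoint list 0 of 24 genes passed over all genes and 0 when adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.310), and BUB1, a checkpoint kinase, stood at 188 ± 4.86 against 236 ± 22.3 CPM (−0.33, SE 0.13, adjusted p = 0.212). The counts were also 0, over all genes and adjusted over the list alone, among 20 mitotic cyclins and kinesins, 26 genes of DNA replication and G1/S, 28 genes of double-strand break repair, 39 proteasome subunits, 22 genes of drug efflux and glutathione detoxification, 25 genes of the ATF4 response, 19 cytosolic heat shock proteins, 26 interferon-stimulated genes, 33 nuclear respiratory chain subunits and 10 histone genes. Their camera adjusted p-values lay between 0.161 and 0.970, and each held 0 to 6 genes at an unadjusted p under 0.05 and 0 to 2 called by DESeq2. With the preset correlation, several of these results changed when 1 library was left out. Without EV replicate 3, camera called the spindle checkpoint (adjusted p = 0.000428), mitotic (adjusted p = 0.00381), replication (adjusted p = 0.00118), double-strand break repair (adjusted p = 0.0304), proteasome and respiratory chain lists lower (adjusted p = 0.00487 for both) and the interferon list higher (adjusted p = 2.75e-05). The ATF4 list was lower without EV replicate 2 (adjusted p = 0.00513) and the histones without TRIP13-OE replicate 1 (adjusted p = 0.00332). With an estimated correlation none of these 9 lists was called in those settings (adjusted p = 0.589 to 0.657 without EV replicate 3, 0.916 and 0.899 for the last 2). In the plasma cell and myeloma list, TNFRSF13B, a receptor for the survival factors BAFF and APRIL, rose from 0.409 ± 0.0889 to 6.80 ± 0.434 CPM while SDC1 and FKBP11 fell. Adjusted over the list alone, 3 of its 27 members rose and 10 fell (camera adjusted p = 0.189). In the BCL2 family, the pro-apoptotic gene BMF rose from 48.6 ± 26.1 to 229 ± 28.4 CPM (2.24, SE 0.39, adjusted p = 0.0479) and was the 1 of 14 members that passed on either count (camera adjusted p = 0.713). Among 27 immediate early genes, IER5 and JUNB rose by 1.30 (SE 0.18) and 0.86 (SE 0.12), 3 rose when adjusted over the list alone, and camera gave an adjusted p of 0.359. Of 23 p53 target genes, 0 passed over all genes (6 at an unadjusted p under 0.05, 5 by DESeq2), and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.549).

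Markers of other cell types moved in both directions. Of 6 tested myeloid markers, CD68 was the 1 that fell over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.455). ITGAX, the member that rose on that count, stood at 19.6 ± 6.74 against 1.62 ± 2.53 CPM (log2 fold change 3.60, SE 1.14; 6.83 without EV replicate 1, which held 4.54 CPM), and LYZ, an abundant myeloid transcript, at 0.0736 against 0.0747 CPM. Of 7 stromal and epithelial markers, 0 passed over all genes, 3 were higher by DESeq2 and at an unadjusted p under 0.05, and 3 rose when adjusted over the list alone (camera adjusted p = 0.207; 0.0435 without EV replicate 3, and 0.589 there with an estimated correlation), with COL1A1 at 5.36 ± 3.12 against 1.23 ± 0.727 CPM. Too few members could be tested in the list of T and NK cell markers, where PRF1 stood at 0.51 (SE 1.16, adjusted p = 0.838; 4.23 without EV replicate 1, adjusted p = 0.00537, and −0.04 and −0.02 without EV replicates 2 and 3), and in the immunoglobulin list, where JCHAIN stood at −1.13 (SE 0.25, adjusted p = 0.0803) and IGLL5 at 0.64 (SE 0.22, adjusted p = 0.163). The tables used here held 0 of the 13 mitochondrially encoded genes.

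Because stable lines can differ in copy number, the called genes were counted on each chromosome. With all 6 libraries, 0 of 46 tests over 23 chromosomes and both directions passed (Fisher's exact test on the edgeR calls, two-sided), 4 had an unadjusted p under 0.05, and chromosome 6, with 15 higher genes against 7.47 by its share, had the smallest p (p = 0.0118, adjusted p = 0.407). Without EV replicate 1, 18 of the tests passed. Of 425 tested genes on chromosome 14, 140 were then higher against 50.8 by its share (adjusted p = 1.20e-29), and of 699 on chromosome 12, 151 were lower against 76.8 (adjusted p = 1.38e-15). Genes of chromosome 14 had a median deviation from the mean of the 6 libraries of −0.28 in EV replicate 2 and −0.31 in EV replicate 3, against 0.16 in EV replicate 1 and 0.14 to 0.16 in the TRIP13-OE libraries, on the log2 scale. Neighbouring genes are not independent, so these p-values describe these libraries.

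**Figure D4:**
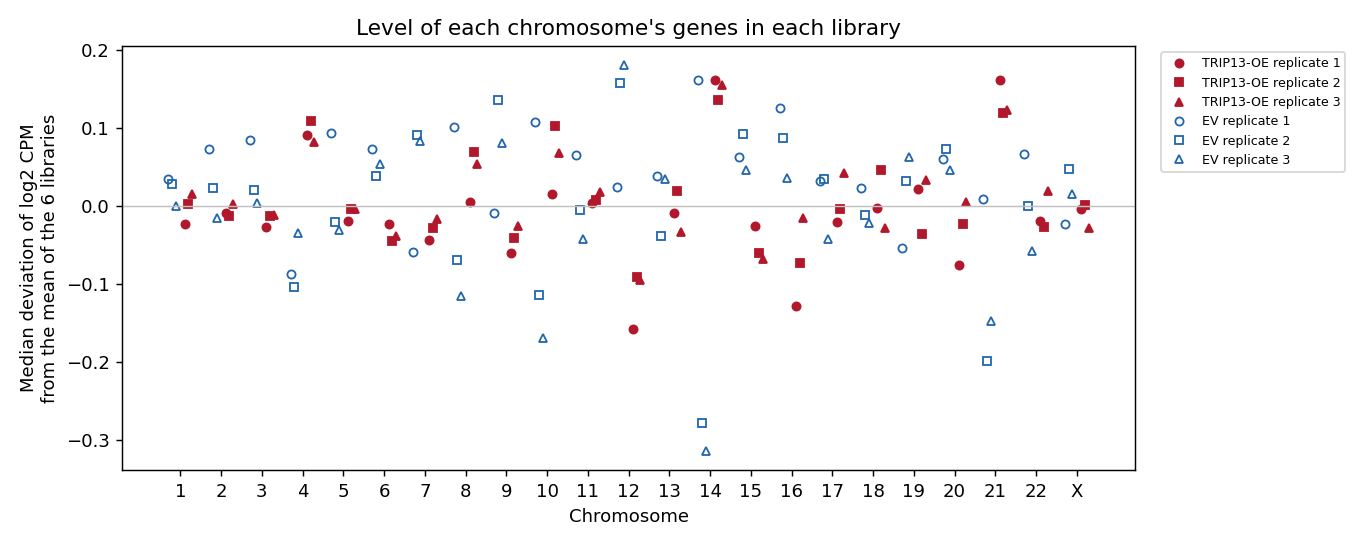
Median deviation of log2 CPM from the mean of the 6 libraries over the genes of each chromosome, for each TRIP13-OE library (filled red) and EV library (open blue). On chromosome 14, EV replicates 2 and 3 lie at −0.28 and −0.31 and the other libraries between 0.14 and 0.16.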

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

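Limma-voom with sample weights, the gene lists under upper-quartile factors and library totals, and an estimated correlation with 1 library left out, were chosen after the data were seen, and what would count for chance in the splits was written after their results were known. All 180 called genes kept their direction in every setting where they were tested. Among 62 named genes, 1104 combinations of gene and setting gave 785 with the same call, 288 that lost it, 26 that gained it and 5 that turned sign, all of RPS3. Its log2 fold change turned to 0.0455 with upper-quartile factors, 0.0323 with library totals only, and 0.0321, 0.0322 and 0.0321 with limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, where composition is not scaled. The median over all genes was −0.02 with TMM and 0.07 with upper-quartile factors. The counts with upper-quartile factors were 209 higher and 28 lower (88.2% higher, against 81.7% with TMM).

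Against 147 higher and 33 lower genes, DESeq2 called 713 and 598 (54.4% higher), and sample weights called 2451 and 2116. Limma called 168 and 20 on log2(FPKM + 1), 130 and 16 on log2(FPKM + 0.1), and 338 and 29 without a filter. At an adjusted p under 0.01, 5 and 0 remained. Leaving out 1 library gave 1 to 1519 higher and 0 to 1400 lower genes, the highest without EV replicate 1 and the lowest without TRIP13-OE replicate 2 or 3 or EV replicate 2, where COL9A2 was the gene left. TRIP13's log2 fold change ranged from 3.36 to 3.98 when 1 library was left out. Fewer libraries leave less power, and without EV replicate 1 the EV libraries left are more alike; the cause of the other shifts was not tested.

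The replicate numbers gave no sign of pairing. Libraries with the same number deviated from their group means with correlations across genes of −0.35, −0.13 and −0.29. These values depend on each other, as deviations within a group sum to 0, so a batch shared by number stays open. With the replicate block, edgeR called 0 genes higher and 0 lower (1731 at an unadjusted p under 0.05), TRIP13 stood at 3.75 (adjusted p = 0.110), and 7 lists and 0 chromosomes were called.

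Of the 7 lists called, an estimated correlation left 0 and fry 0 (lowest adjusted p 0.0504; 1 and 6 lists at an unadjusted p under 0.05), and leaving out 1 library gave 6 to 15, the highest without EV replicate 3, and 0 in each case with an estimated correlation (0 to 2 lists at an unadjusted p under 0.05). The chromosome tests passed 0 to 18 times when 1 library was left out, the highest without EV replicate 1. With 3 libraries per group and the spread and depth of these libraries, edgeR recovered 26.9% of simulated genes with a log2 change of 1. These genes had a mean log2 CPM of at least 2, and the simulation left out the shared differences among the EV libraries. Little can therefore be said of 2-fold changes that did not pass.

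There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split called 180 genes and the highest other split 0, so 1 split was as high. At an unadjusted p under 0.05 the contrast was small. The real split had 2533 genes, and TRIP13-OE replicate 1 with EV replicates 2 and 3 had 2092. For the lists, 7 of the 10 splits called at least the 7 of the real split, the highest 15. The number of lists called is therefore no evidence for the real grouping. The called lists had estimated correlations of 0.175 to 0.816, above the preset 0.01. Whether this or differences among the libraries led to the calls in other splits was not tested. For the chromosomes, all 10 splits gave 0, which was bound to happen in the other splits, as they called 0 genes.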

Other observations

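All tests here were chosen after the patterns were seen; for gene length, the outcome that would count against it was set before its result. The MHC class II genes, taken as all tested genes with a symbol starting with HLA-D, rose at 8 of 11, against 139 of 12471 other genes; the group was chosen because members had been seen to rise, so no p-value is given. HLA-DPB1 stood at 28.6 ± 5.07 CPM in TRIP13-OE against 1.90 ± 1.46 in EV (log2 fold change 3.91, and 4.73 without EV replicate 1), and HLA-DMB, a chain of the class II peptide exchange factor HLA-DM, at 7.18 ± 1.97 against 1.23 ± 0.362. HLA-DOB, at 1.87 ± 0.918 against 2.21 ± 0.757 CPM, did not pass (adjusted p = 0.825). The close copies among these genes leave the division of reads uncertain.

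Within the EV group, 503 genes differed over 4-fold between EV replicate 1 and both other EV libraries, 143 higher and 360 lower in EV replicate 1, against 20 and 53 genes by the same rule for EV replicates 2 and 3. HIC1, a transcriptional repressor, stood at 107 CPM in EV replicate 1, 4.61 and 2.79 CPM in EV replicates 2 and 3, and 137 to 147 CPM in TRIP13-OE. GNG4, a G protein subunit, stood at 120 CPM in EV replicate 1, 2.15 and 1.68 CPM in the other EV libraries and 32.5 to 41.6 CPM in TRIP13-OE. FGF13 and LSAMP had 0 counts in EV replicate 1, at 44.3 and 45.4 CPM and at 22.5 and 33.6 CPM in EV replicates 2 and 3. SFRP2, a secreted WNT modulator, stood at 0.738 CPM in EV replicate 1 and at 66.1 and 77.9 CPM in the others. The TRIP13-OE mean was nearer to EV replicate 1 at 271 of the 503 genes and nearer to the other EV libraries at 232.

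A mixture of TRIP13-OE RNA in EV replicate 1 is argued against as the cause. With EV replicate 3's level taken for the EV cells, TRIP13 allows a share of at most 7.18%. Of the 503 genes, 100% needed more or could be made by no share. For the 360 genes lower in EV replicate 1 this was bound to hold, as so small a share cannot lower a gene over 4-fold. It also held for all 143 higher genes. So small a share raises a gene over 4-fold only where TRIP13-OE lies far above EV replicates 2 and 3. This outcome was therefore nearly fixed by how the genes were picked. What argues against a mixture is that 503 genes differed so much although TRIP13 allows so small a share. EV replicates 1 and 2, the EV libraries closest in total counts, differed over 4-fold at 625 genes, and EV replicates 2 and 3, the furthest apart, at 98, which argues against depth. After a smooth trend on gene length was removed, 95.8% of the 503 genes stayed over 4-fold apart, which argues against length. TRIP13 stood at 145 CPM in EV replicate 1 against 1249 to 1332 CPM in the TRIP13-OE libraries. This argues against a TRIP13-OE library under a wrong label. A separately derived culture or subclone, a different batch and another kind of wrong label stay open for EV replicate 1. No test here separates them.

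On chromosome 14, 69.5% of 344 genes were lower in both EV replicates 2 and 3 than in EV replicate 1, against 41.9% of the other genes and at most 52.3% in 10000 random sets of the same size. The shares were 60.0%, 71.9% and 76.3% in the first, middle and last of 3 equal parts of the chromosome by gene order, with at most 58.8% in random sets of 114 genes. The median shifts from EV replicate 1 were −0.46 and −0.45 on the log2 scale, and 0.00, −0.06 and −0.04 in TRIP13-OE replicates 1 to 3. A lower copy number of chromosome 14 in part or all of the cells of EV replicates 2 and 3 may account for this; DNA was not measured here, the chromosome was picked for its shift, and regulation along the chromosome stays open.

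The higher B cell marker and NF-kB lists and the lower unfolded protein response and cholesterol lists were weighed against technical sources. LYZ, CD14, S100A9, CD22 and CD79B were picked as markers after their levels were seen. Their highest mean in TRIP13-OE was 0.595 CPM, against 324 CPM for CD74. This argues against admixed cells that carry these transcripts as the source of the class II transcripts. Other myeloid and B cell markers moved in both directions, among them ITGAX, SPIB and BCL6 higher and CD68 lower in TRIP13-OE. Other admixed cells thus stay open. A scaling factor moves all genes of a library alike, while in each of the 9 pairs of a TRIP13-OE and an EV library the medians of the higher lists lay at least 1.55 above those of the lower lists on the log2 scale, which argues against scaling as the cause of both directions. EV replicate 1 lay beyond all 3 TRIP13-OE libraries on the side of the list at 73 of 86 members (84.9%). The counts ran from 7 of 12 B cell markers to 25 of 26 NF-kB targets. At most of these members the difference was thus not confined to EV replicates 2 and 3. The lists were picked for a change with EV replicate 1 in the EV group, which favours this outcome. The counts are therefore no separate evidence for the lists. The share over all tested genes was not computed. A response to TRIP13 and selection of subclones when the stable lines were made both stay open and were not tested against each other, since the vector and the culture history differ together.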
